A study of Mus musculus with 8 samples.

How the data were processed

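RNA was measured in the inguinal white adipose tissue of C57BL/6 mice that had been fed a 60% high fat diet for more than 12 weeks. Adenovirus had been injected into the fat pad, carrying either GFP alone or miR-30a with GFP. The labels gave 4 libraries of each group. Replicates were numbered in accession order within a group, so the numbers name libraries and pair nothing. Each library had its own title number, but nothing in the labels said what separates the samples (animal, pad or day), so p-values measure only the spread between these libraries, which may be technical.

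The deposited table holds 1 value per gene and library for 22520 gene rows, restricted to coding genes and quantile normalized according to its own name. The unit was taken to be FPKM made by the authors (fragments scaled by transcript length and by mapped fragments). That unit was inferred from Cufflinks in the submitters' processing notes and from the continuous values, and no header states it. The submitters' processing notes name TopHat2 version 2.0, Cufflinks version 2.0 and the mm10 build, without roles or parameters. The annotation and any filter on rows are not given in the sources used here. In each library the highest value was 23849.8, and of the 100 highest values 18 were identical in every library. Quantile normalization gives all libraries nearly the same distribution, so a change shared by most genes cannot be seen, and a library's total (577853 to 594491 FPKM) says nothing of its depth. With no counts, the sequencing depth is unknown, and no counting interval can be given. Of the rows, 4880 were listed at 0 in all 8 libraries. An exact 0 can be a failed estimate. Among genes with a median above 20 FPKM, Scd1 alone had one.

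Gene identifiers were joined to GENCODE M21, which uses GRCm38, the assembly that mm10 names; 21740 identifiers matched. Coordinates are from that annotation. Older symbols in the table were matched through the identifiers (8 listed genes, Emr1 for Adgre1 among them). Values were transformed as log2(FPKM + 1), and a fold change on this scale understates the change of low genes. The 12015 genes with a mean of at least 1 FPKM over the 8 libraries were tested with limma 3.58.1 in R 4.3.3 (linear model per gene, moderated variance with a trend on mean expression). Tests were two-sided, with the Benjamini-Hochberg adjustment and a threshold of 0.05. Means ± SD are in FPKM with n = 4 per group, and SEs are those of the limma fold change.

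Fixed before the data were examined were 33 gene lists covering programs of adipose tissue, marker genes of cell types a fat pad could hold, and signs of tissue handling. Of 460 list entries, 455 had a row in the table. Each list was tested with camera (limma) at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. The score of a list in a library is the mean log2(FPKM + 1) of its tested members. Scores were compared by an exact permutation test over the 70 assignments of libraries, two-sided, whose smallest possible p is 0.0286. For seed sites, the longest annotated 3' UTR of each gene was searched for matches to positions 2 to 8 of miR-30a-5p and miR-30a-3p (7mer-m8, 7mer-A1 and 8mer sites). A 3' UTR was annotated for 11811 tested genes (98.3%), and the others count as not searched. The difference in mean fold change between genes with and without a site was tested by the same exact permutation, and was set beside that of every 7-mer found in at least 200 genes.

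The text names the 6 genes per direction with the smallest p, since fewer had passed the threshold, 8 genes fixed in advance (Nrip1, Pparg, Adipoq, Lep, Ucp1, Tnf, Ccl2 and Adgre1), and up to 4 members with the smallest p of each list described. Some genes that the rule takes in are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

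The steps were tested on simulated values for the 12015 genes of the comparison of miR-30a against GFP control, drawn independently with each gene's own mean and spread. Of 200 changed genes, 50 for each size, limma recovered 44% at a log2 change of 1, 90% at 2, and 100% at 3 and at 4. It also called 10 unchanged genes among 177 calls. Of 30 random lists of 20 genes, camera called 0, and it called the 1 list that had been shifted. Genes drawn independently do not vary together, so this does not show how often camera falsely calls lists whose genes do. In the real data 0 lists passed with an estimated correlation. The recovery shares are for genes picked at random and need not hold for genes with a larger spread.

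Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at a mean of 5 FPKM, centring on the library median, a trimmed-mean scaling of each library, each library left out in turn, weights per library, variance fits without trend and with robust estimation, looser thresholds, 8mer sites only, and 3' UTR length and GC content as covariates. Added after seeing the data were a fit without the 2 libraries highest in B cell markers, B cell and skeletal muscle scores as covariates, and Scd1 left out. Count models were not run because the unit is not counts. Among listed genes, Irf8, Nlrc5, Acta1, Cox4i1 and Flg were not analysed here. The virus dose and the level of mature miR-30a in the pads were not analysed here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.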

Results

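RNA sequencing compared inguinal white fat pads of obese C57BL/6 mice injected with adenovirus carrying miR-30a and GFP (4 libraries) with pads injected with GFP adenovirus alone (4 libraries). The mice had eaten a 60% high fat diet for more than 12 weeks. Inguinal white adipose tissue is a subcutaneous depot that holds adipocytes, their progenitors, vessels and immune cells, and often a lymph node. miR-30a is a microRNA that pairs through its seed with sites in 3' UTRs. The comparison asks which transcripts differ when miR-30a is supplied to the pad. Sequencing depth is unknown because the deposited table holds quantile-normalized FPKM. Spearman correlations of libraries over genes had a median of 0.934 within groups and 0.927 between groups.

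Interferon-response genes were lower in the miR-30a pads. Of the 34 genes on this list, 32 were tested, and all 32 were lower, with a mean log2 fold change of -2.07 and a median of -1.93. The list's score was 5.09 ± 1.17 (SD, n = 4) log2 units in GFP controls and 3.02 ± 0.34 (SD, n = 4) with miR-30a, a 4.20-fold lower geometric mean. Each control library (3.72 to 6.56) lay above each miR-30a library (2.76 to 3.53), and the exact permutation p was 0.0286, the smallest the design allows, or 0.629 adjusted over the 33 lists. The list passed camera with the preset correlation (adjusted p = 1.32e-55). It did not pass otherwise, with adjusted p = 0.446 with an estimated correlation (0.0135 unadjusted) and 0.466 by fry. At an unadjusted limma p under 0.05 stood all 32 genes. Adjusted over the list alone 32 of 32 passed the threshold, which follows from the unadjusted result and adds nothing to it. Over all genes 0 of 32 passed. Without any single miR-30a library the exact p was 0.0571, with differences of -2.24 to -1.99. Without any single control library it was 0.0286, with differences of -2.53 to -1.58. The groups overlapped in none of these fits, so their p-values say little of how far the list depends on a library.

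The 4 interferon-response genes with the smallest p were Ifit3, Ifit1, Igtp and Stat2. Ifit3, an antiviral RNA-binding protein induced by interferon, had 78.8 ± 63.4 FPKM in controls and 11.6 ± 1.74 with miR-30a, a log2 fold change of -2.37 ± 0.45 (SE; limma adjusted p = 0.652). Its relative Ifit1 had a log2 fold change of -2.50 ± 0.49. Igtp, an interferon-inducible GTPase that acts on vacuoles of pathogens, had 286 ± 277 FPKM against 12.1 ± 10.8, with a log2 fold change of -4.08 ± 0.84. Its locus on chromosome 11 (58199556 to 58207591, plus strand, GRCm38) overlaps that of Irgm2 (58199618 to 58222782), so reads of the pair may not be told apart. Stat2, a transcription factor of type I interferon signalling, had a log2 fold change of -1.78 ± 0.39.

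**Figure D1:**
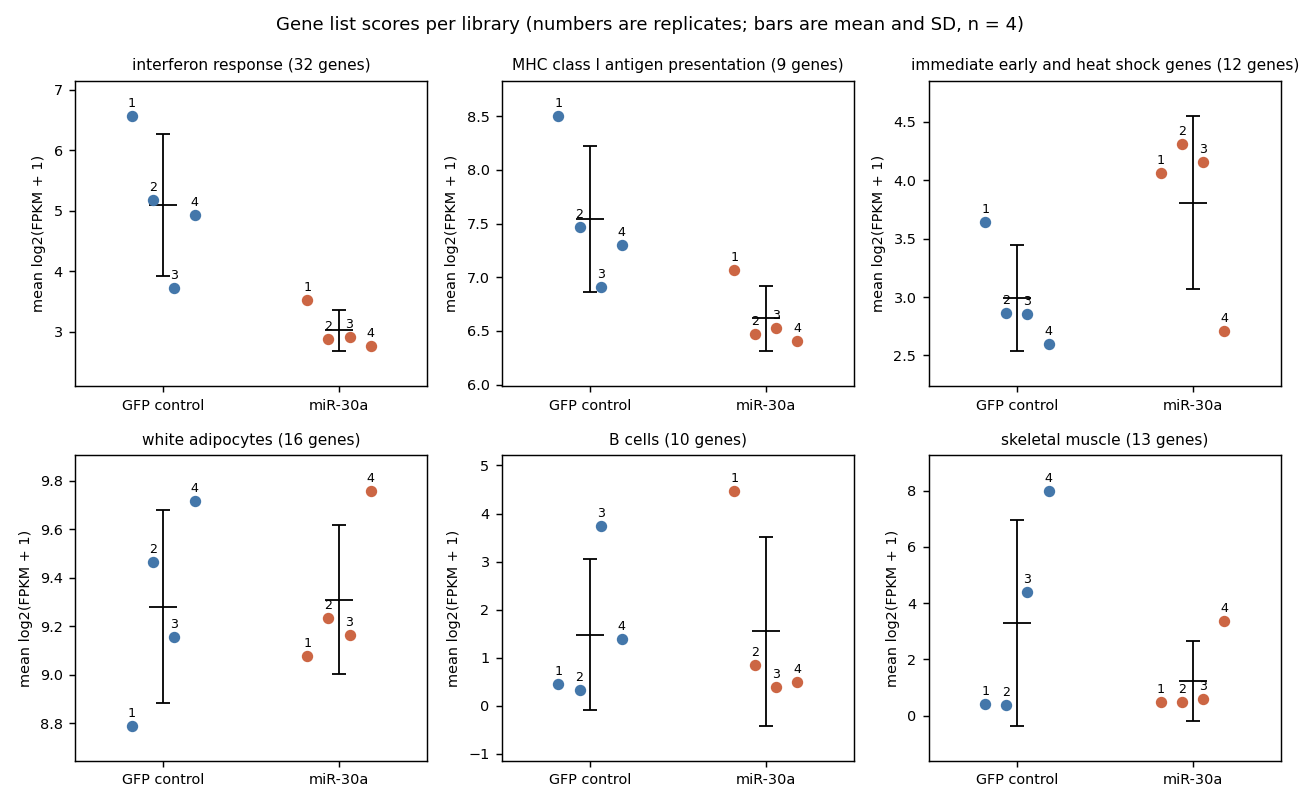
Mean log2(FPKM + 1) of 6 gene lists in each library (points, numbered by replicate) for GFP control and miR-30a pads, with mean and SD (n = 4). Interferon scores do not overlap between groups (3.72 to 6.56 against 2.76 to 3.53), B cell scores are high in GFP control 3 (3.74) and miR-30a 1 (4.47), and the skeletal muscle score is highest in GFP control 4 (7.99).

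MHC class I antigen presentation genes load peptides for display to cytotoxic T cells. All 9 members had negative fold changes (mean log2 -0.93), 5 of them at an unadjusted p under 0.05, and those 5 passed when adjusted over the list alone. The camera adjusted p was 3.02e-09, but adjusted p = 0.693 with an estimated correlation, and the exact p of the score was 0.0571. Without GFP control 1 the mean was -0.61. The peptide transporter subunits Tap1 and Tap2 had log2 fold changes of -1.97 ± 0.53 and -1.24 ± 0.40, and the immunoproteasome subunits Psmb9 and Psmb8 -1.60 ± 0.44 and -1.24 ± 0.45 (SE; limma adjusted p = 0.741 to 0.9998). MHC class II genes had a mean log2 fold change of -0.23 (7 of 10 lower, 0 adjusted over the list alone). Their camera adjusted p was 0.0391, with adjusted p = 0.866 with an estimated correlation, and the mean turned to 0.034 without miR-30a 4. Of 21 alternatives, 8 others ended this call, among them leaving out GFP control 1, GFP control 3 or miR-30a 3 (adjusted p = 0.202, 0.317 and 0.320). The mean was -0.024 without GFP control 3 and -0.051 without miR-30a 3, and it was -0.63, -0.36 and -0.34 without miR-30a 1, GFP control 2 and GFP control 4.

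Inflammatory cytokines and chemokines had a mean log2 fold change of -0.77, with 18 of 21 genes lower, 4 of these at an unadjusted p under 0.05 and 0 adjusted over the list alone. Camera gave an adjusted p of 2.56e-06, with adjusted p = 0.693 with an estimated correlation. The exact p of the score was 0.229. Without GFP control 1 the mean was -0.35. Ifng, the type II interferon made by T and NK cells, had 14.2, 5.43, 0.159 and 3.71 FPKM in the control libraries and 0.271, 0.157, 0 and 0 with miR-30a (limma adjusted p = 0.893). The chemokines Ccl3, Ccl4 and Ccl8 had log2 fold changes of -2.13 ± 0.68, -1.97 ± 0.75 and -1.85 ± 0.78. Tnf had a log2 fold change of -0.95 ± 0.45 and the monocyte attractant Ccl2 of -1.03 ± 0.84 (limma adjusted p = 0.9998 for both). Without GFP control 1, where they were at 8.08 and 421 FPKM, these were -0.53 and -0.30.

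Macrophage lists had smaller mean fold changes than the interferon, MHC class I and cytokine lists. General macrophage markers had a mean log2 fold change of -0.43, with 12 of 14 lower and 0 adjusted over the list alone (camera adjusted p = 0.000396, adjusted p = 0.693 with an estimated correlation). Fcgr1, a high-affinity IgG receptor, had a log2 fold change of -1.98 ± 0.57. The complement subunits C1qa, C1qb and C1qc had -0.52 ± 0.23, -0.51 ± 0.28 and -0.46 ± 0.24. Adgre1, which encodes F4/80 and is listed as Emr1, had -0.38 ± 0.41. Without miR-30a 4 this list's adjusted p was 0.201 and its mean -0.21, and with weights per library they were 0.0881 and -0.26. M1 markers had a mean of -0.61, with 8 of 9 lower and 1 past the threshold adjusted over the list alone, Fpr2, a formyl peptide receptor (log2 fold change -1.81 ± 0.42). Their camera adjusted p was 0.000233, with adjusted p = 0.693 with an estimated correlation, and their mean was -0.33 without GFP control 1. With a filter at a mean of 5 FPKM their mean was -0.28 and the adjusted p 0.196, and with pseudocounts of 0.1 and 5 the mean was -1.10 and -0.24. M1 markers share Tnf, Il1b, Nos2 and Il12b with the cytokine list. M2 markers (mean -0.16, camera adjusted p = 0.0575) and lipid-associated macrophage genes (mean 0.02, adjusted p = 0.985) did not pass camera.

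T cell markers had a mean log2 fold change of -0.55, with 15 of 16 lower and 0 adjusted over the list alone (camera adjusted p = 0.0492, adjusted p = 0.866 with an estimated correlation). Gzmb, a protease of cytotoxic T and NK cells, had 22.1 ± 21.5 FPKM in controls and 0.932 ± 0.55 with miR-30a, a log2 fold change of -2.88 ± 0.85. T cell and B cell scores were highest in the same libraries, GFP control 3 (3.28 and 3.74) and miR-30a 1 (4.25 and 4.47). Without GFP control 3 the T cell mean was -0.18, and without miR-30a 1 it was -1.42. The call of the T cell list was lost in 12 of 21 alternatives, with a mean of -1.13 at a pseudocount of 0.1 and of -0.17 at 5 (adjusted p = 0.408). The B cell list had a mean of 0.07 (camera adjusted p = 0.985).

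Adipocyte lists other than lipogenesis did not pass the list test. White adipocyte markers had a mean log2 fold change of 0.03 over 16 genes (camera adjusted p = 0.910). Adiponectin (Adipoq) had 2060 ± 263 FPKM in controls and 1551 ± 290 with miR-30a, a log2 fold change of -0.42 ± 0.17 (limma adjusted p = 0.9998). Leptin (Lep) and Pparg, the master regulator of adipocyte differentiation, had log2 fold changes of 0.16 ± 0.29 and 0.33 ± 0.29. Fabp4, the fatty acid carrier of adipocytes, had -0.18 ± 0.19. Nrip1, a corepressor of oxidative genes in fat, had 0.17 ± 0.27. Thermogenic adipocyte genes had a mean of -0.06 over 15 genes and a median of 0.02 (camera adjusted p = 0.462). Ucp1, the uncoupling protein of brown and beige fat, was at 0.867 ± 0.80 FPKM in controls and 1.93 ± 3.27 with miR-30a. Lists with camera adjusted p from 0.428 to 0.910 were oxidative phosphorylation and TCA cycle (mean -0.02), fatty acid oxidation (-0.10, median 0.05) and insulin signalling (-0.12, median 0.12).

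Lipogenesis genes had a mean log2 fold change of 0.39, with 13 of 17 higher and 0 adjusted over the list alone. Camera gave an adjusted p of 0.00746, with adjusted p = 0.693 with an estimated correlation. The exact p of the score was 0.0571. Fatty acid synthase (Fasn) had 364 ± 134 FPKM in controls and 561 ± 104 with miR-30a, a log2 fold change of 0.68 ± 0.28 (limma adjusted p = 0.9998), and ATP citrate lyase (Acly) had 0.35 ± 0.19. Scd1, the stearoyl-CoA desaturase, was listed at 0 in GFP control 4 and at 3308 to 5920 FPKM in the other 7 libraries. Without Scd1 the mean was 0.21 (12 of 16 higher, camera adjusted p = 0.0142, exact p = 0.371). The list's adjusted p was 0.168 without GFP control 1, 0.0509 without miR-30a 2, 0.0561 without miR-30a 4 and 0.0686 with weights per library.

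Immediate early and heat shock genes respond to stimulation and to the handling of tissue. Of 12 members 9 had positive fold changes with miR-30a (list mean log2 0.82), 6 of these at an unadjusted p under 0.05, and 4 passed when adjusted over the list alone. Camera gave an adjusted p of 4.34e-07, with adjusted p = 0.693 with an estimated correlation. The score was 4.06, 4.31, 4.16 and 2.71 in the miR-30a libraries and 2.60 to 3.65 in controls (exact permutation p = 0.114). Fosb had 0.647 ± 0.52 FPKM in controls and 12.8 ± 9.33 with miR-30a, a log2 fold change of 2.76 ± 0.57, and the phosphatase Dusp1 had 0.76 ± 0.18. Hspa1a and Hspa1b had 1.28 ± 0.37 and 1.34 ± 0.40, and as near-identical heat shock genes these 2 may share reads.

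Skeletal muscle genes had a mean log2 fold change of -2.06, with 13 of 13 lower and 0 at an unadjusted p under 0.05. Their camera adjusted p of 2.04e-05 rested on GFP control 4, without which the mean was -0.50 and the adjusted p 0.175. With weights per library they were -1.10 and 0.0543. With all libraries, adjusted p = 0.693 with an estimated correlation. Mylpf, a myosin light chain of fast muscle, was at 1310 FPKM in GFP control 4 and at 0.576 to 56.9 in the other controls. Other cell type lists did not pass camera. Schwann cells had a mean log2 fold change of -0.47 (camera adjusted p = 0.120), erythroid cells 0.62 (0.250), progenitors and fibroblasts -0.23 (0.336), mural cells 0.07 (0.428), neutrophils 0.39 (0.428), epidermis 0.18 (0.910), mast cells 0.04 (0.910) and endothelial cells 0.02 (0.985). Mammary and other epithelium, with 3 genes tested, had a mean of 0.96 (0.0828). The median of progenitors and fibroblasts was -0.03, with 5 genes higher and 5 lower. The program lists ER stress (0.13, adjusted p = 0.0828), cell cycle (0.08, 0.531), extracellular matrix (0.08, 0.531) and microRNA pathway machinery (0.04, 0.752) did not pass either. Y-linked genes had a mean of 0.06 (adjusted p = 0.733).

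Gene by gene, limma called 0 of 12015 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.652. At an unadjusted p under 0.05 there were 137 genes higher and 316 lower with miR-30a, against 601 given by chance. Of these, 11 higher and 157 lower genes differed at least 2-fold. The groups did not overlap for 263 genes, or 2.19%, where chance gives 2.86%. Without GFP control 3, limma called 28 genes, all lower, with 10 of them on the interferon list (smallest adjusted p = 0.0121). Ifng and Gzmb were among the 28. Without miR-30a 1 the counts at an unadjusted p under 0.05 were 416 higher and 480 lower.

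The 6 lower genes with the smallest p were Tnfsf10, Iigp1, Irgm2, Gm4951, Gm4841 and Ifit3. Tnfsf10, the death ligand TRAIL, had 7.85 ± 2.27 FPKM in controls and 2.69 ± 0.39 with miR-30a, a log2 fold change of -1.23 ± 0.20 (SE). Iigp1, an interferon-inducible GTPase on chromosome 18 (60376027 to 60392634, plus strand), had 450.5 ± 386 FPKM against 13.5 ± 8.12, a log2 fold change of -4.53 ± 0.75. Gm4951 and Gm4841, members of the same GTPase family within chromosome 18 (60212080 to 60273272), had -3.37 ± 0.62 and -4.62 ± 0.86, and reads may be shared among these paralogs. Irgm2 had -3.17 ± 0.55. Each of these had an adjusted p of 0.652.

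The 6 higher genes with the smallest p were B230307C23Rik, Rfx2, Snai1, Fosb, Zfp691 and Tppp3. B230307C23Rik, on chromosome 16 (97997315 to 98031801, plus strand), had 0.231 to 3.59 FPKM in controls and 5.49 to 37.0 with miR-30a, a log2 fold change of 3.19 ± 0.58 (SE). The transcription factors Rfx2, Snai1 and Zfp691 had 0.95 ± 0.18, 0.84 ± 0.17 and 0.67 ± 0.14. Tppp3, a tubulin-binding protein, had 31.4 ± 1.90 FPKM in controls and 46.7 ± 6.77 with miR-30a, or 0.55 ± 0.12. Their adjusted p was 0.652 as well.

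**Figure D2:**
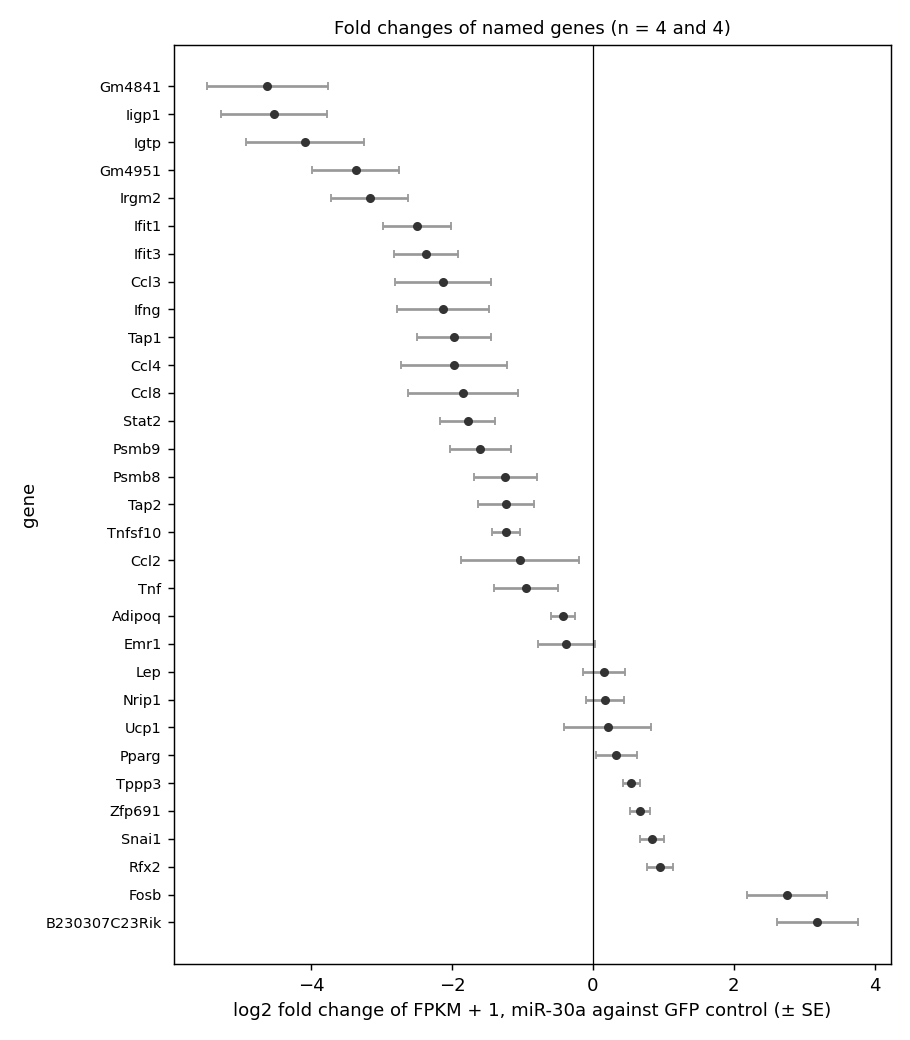
Log2 fold change of FPKM + 1, miR-30a against GFP control, with SE (n = 4 and 4), for genes named by fixed rules. Values run from -4.62 (Gm4841) to 3.19 (B230307C23Rik), and 0 of them passed limma's adjusted threshold.

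Predicted and reported targets of miR-30a did not pass a test of a common shift. Genes reported as targets of the miR-30 family had a mean log2 fold change of 0.06 over 25 genes (camera adjusted p = 0.456), with 16 higher and 9 lower. When adjusted over the list alone, 1 was higher (Snai1) and 1 lower. Part of that list came from knowledge of the study, so it is not independent evidence of a direction. The longest 3' UTR of Snai1 held 1 miR-30a-5p site. Ctgf, a secreted factor of matrix remodelling, had 0.66 ± 0.38. The 2497 genes with at least 1 miR-30a-5p site had a mean log2 fold change that differed from that of the 9314 genes without one by 0.0053 (exact permutation p = 0.8). With 3' UTR length and GC content as covariates the difference was 0.0153 (exact p = 0.200), and for 970 genes with 8mer sites it was 0.0163 (exact p = 0.543). For miR-30a-3p it was -0.0069 (exact p = 0.771). Among 13721 7-mers, the 7mer-m8 and 7mer-A1 matches of miR-30a-5p stood at the percentiles 79.9 and 57.5 from the lowest difference. Those of miR-30a-3p stood at 60.5 and 14.9.

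**Figure D3:**
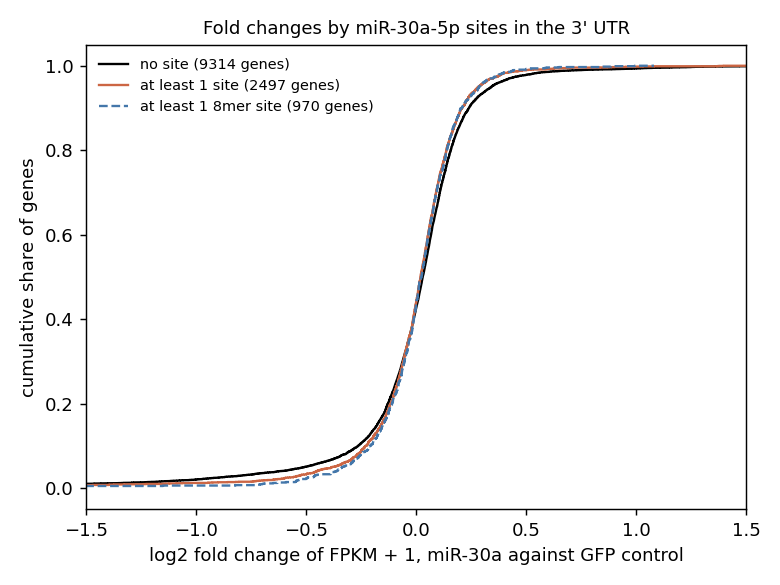
Cumulative share of genes by log2 fold change of FPKM + 1, miR-30a against GFP control, for genes with no miR-30a-5p site in the longest 3' UTR (9314), at least 1 site (2497) and at least 1 8mer site (970). The curves differ in spread, and the means with and without a site differ by 0.0053.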

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

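The test of the immediate early genes below was chosen after the result was seen; the rule that picked out single libraries was fixed before. It compares the highest or lowest of the 4 libraries of a group with the rest (the gap to the nearest library over the whole range, against Dixon's 95% critical value) and picks out about 1 in 20 groups by chance; here it picked out 27 of 166 groups.

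Libraries with lymphoid transcripts stood apart. miR-30a 1 had scores of 4.25 for T cells and 4.47 for B cells, against at most 0.79 and 0.848 in the other miR-30a libraries. It also had the highest levels in its group of Lck (43.2 FPKM), Nkg7 (36.4), Tnfrsf9 (2.09), Ccl3 (1.04), Psmb8 (80.8), Psmb9 (27.7), Tap1 (24.6) and Igtp (28.2), and the lowest of Fasn (406).

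Muscle transcripts were high in GFP control 4, GFP control 3 and miR-30a 4, with skeletal muscle scores of 7.99, 4.41 and 3.36 and at most 0.613 in the other 5 libraries. GFP control 4 had Mylpf at 1310, Myh4 at 308, Actn3 at 135 and Tcap at 68.9 FPKM. GFP control 3 had Mylpf at 56.9 and Myh4 at 34.6 FPKM. miR-30a 4 had Mylpf at 22.3, Myh4 at 9.22, Tcap at 3.54 and Actn3 at 2.26 FPKM. Epidermis scores were high in miR-30a 4 (3.82) and, less so, in GFP control 4 (1.9), while the epithelial score was 2.60 in miR-30a 4, 1.69 in miR-30a 2 and at most 0.379 in the other 6 libraries. Among controls, whose range was narrow, GFP control 1 had 0.323. Other single libraries were miR-30a 3 for Ucp1 (6.82 FPKM) and Rfx2 (8.19 FPKM), and GFP control 1 for Tnf (8.08 FPKM).

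Immediate early and heat shock genes were high in miR-30a 1, 2 and 3, while miR-30a 4 had a score of 2.71, within the range of the controls. These genes respond within minutes to the dissection of tissue, so differences in handling may account for the pattern, and so may an effect of miR-30a. The exact permutation p of 0.114 decides neither, because the groups overlap through 1 library and the labels give no time of dissection. The explanations cannot be told apart here.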

How the results depend on the processing

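Fits without 2 libraries, with cell type covariates and without Scd1 were chosen after seeing the data; causes were not tested. By limma, 0 genes were higher and 0 lower under every alternative at the same threshold, except that 0 to 28 were lower with one library left out (28 without GFP control 3) and 30 without the 2 libraries highest in B cell markers; 42 higher and 239 lower had an unadjusted p under 0.05 with a 1.5-fold change. Lists past the threshold were 7 to 14 with one library left out, but 0 with an estimated correlation and 0 by fry. The interferon list did not pass by either (adjusted p of 0.446 and 0.466), and its mean of -2.07 is not refitted by these methods. Its score difference was -2.53 to -1.58 with one library left out and -2.70 without those 2 libraries (exact p = 0.1, the smallest that 3 against 3 allows). The site difference ranged from -0.0105 (without GFP control 4) to 0.0206, and was -0.0051 with no filter and -0.0131 with library weights. Directions turned for MHC class II (-0.63 to 0.034 with one library left out), and among 66 named genes for 5: Nrip1 (-0.020 to 0.35), Lep (-0.033 to 0.38, and -0.079 with weights), Ucp1 (-0.44 to 0.51, and -0.027 with covariates), Il7r (-0.14 to 0.96, and -0.084 with covariates) and Cpt1b (0.059 with weights). Of 1241 gene alternatives 9 reversed and 18 crossed the threshold. Robust variance fits of lists (camera has none), count models, and the muscle list with its own score as covariate were not run. Depth is unknown, so its limit on low genes was not assessed.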

Other observations

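Splits of the libraries were planned before the results were seen, except the comparison of the smallest camera p of any list. That comparison was chosen afterwards. So were the tests of lymph node tissue, of a single control library, of macrophage number and of direct repression, and the genes named in the next 2 paragraphs.

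Some genes outside the fixed lists had negative fold changes that did not pass the threshold. The GTPases Gbp10 and Gbp6 had log2 fold changes of -3.61 ± 0.75 and -3.27 ± 0.70 (SE; limma adjusted p = 0.652 for both). Gbp7 had -2.42 ± 0.55 and Tgtp1 -2.94 ± 0.78 (limma adjusted p = 0.652 and 0.741). On the interferon list, the chemokine Cxcl10 ran from 19.1 to 1050 FPKM in controls and from 3.39 to 23.8 with miR-30a, and Cxcl9 from 27.1 to 771 and from 9.87 to 22.2. Ifnb1, a type I interferon, was listed at 0 in all 8 libraries. Without GFP control 3 limma called 28 genes and without that library and miR-30a 1 it called 30, of which 19 were shared.

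Genes typical of other tissues were high in 1 to 3 libraries each, and where their RNA came from was not tested. The B cell gene Cd79a was at 68.4 FPKM in GFP control 3 and 102 in miR-30a 1, with 0.287 to 5.41 elsewhere. Ccl21a, a chemokine of lymph nodes, was at 185 and 512 in these libraries, and Glycam1, a product of lymph node vessels, at 21.3 and 79.9, with 0 in the other 6. Tnnt3, a fast muscle troponin, was at 1080 FPKM in GFP control 4, 66.7 in GFP control 3 and 29.6 in miR-30a 4. Liver genes were high in miR-30a 2, with Alb at 326 FPKM (5.06 to 22.2 elsewhere), Apoa2 at 167 and Ttr at 47.4.

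Results were counted again on the 35 splits of the 8 libraries into groups of 4. For the interferon list, 1 of 35 splits, the real one, gave a camera p as small (-log10 p of 56.4, against 43.9 for the highest other). Over all 33 lists, 1 of 35 splits, again the real one, gave any list a camera p as small (highest other 43.9). These splits are the same assignments as in the exact permutation test of the score (p = 0.0286, or 0.629 adjusted over the 33 lists). They are not separate evidence, and 1 of 35 is the smallest share they can give. Chance is therefore not excluded by them. For the count of genes at an unadjusted p under 0.05, 21 of 35 splits gave at least as many (453 in the real split, 1695 in the highest other). Chance is not excluded for this count. For genes past the adjusted threshold, the real count was 0, which all 35 of 35 splits must reach (highest other 1), so the splits say nothing of it. For lists past the threshold in camera, 26 of 35 splits gave at least the real 10 (highest other 20). Chance is therefore not excluded for the number of lists.

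A lower interferon response with miR-30a is a hypothesis that several technical explanations may rival. The B cell score was nearly equal between groups (difference 0.067), which argues against lymph node tissue as the whole cause. With so balanced a score as a covariate the difference could hardly move, and it was -2.06 (SE 0.636) against -2.07 without it. A single high control as the whole cause is argued against by the size of the difference without GFP control 1, which was -1.58. The exact p of that fit (0.0286) adds little. The groups did not overlap with all libraries, so they could not overlap without this one. Fewer macrophages were tested in 2 ways. The interferon minus macrophage score, tested first, differed by -1.64 with overlapping groups (exact p = 0.0857) and settled nothing. The macrophage score itself, tested next because the first test had settled nothing, differed by -0.431 (SE 0.313), against -2.07 for the interferon score. This argues against macrophage loss as the whole cause only if general macrophage markers and interferon genes would fall alike. That was not tested, so fewer or different macrophages stay open. Differences in virus dose or in the response to the vector between groups were not tested and stay open beside an effect of miR-30a.

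A hypothesis that lower transcripts are direct targets of miR-30a-5p was tested by their sites, which were not more frequent among lower genes. The test cannot decide the question, because genes at this threshold, in both directions, numbered 453 against 601 given by chance. The level of mature miR-30a in the pads was not analysed either. Of 309 lower genes (unadjusted p under 0.05) with a 3' UTR, 64 held a site, or 20.7%, against 21.1% of all tested genes. With 3' UTR length and GC content as covariates the odds ratio was 0.966 (95% interval 0.712 to 1.31), which leaves room for a small enrichment. On the interferon list 3 of 32 genes held a site. Sites outside 3' UTRs and repression of translation could not be seen in these values.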
